A study of Mus musculus with 2 samples.

How the data were processed

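Liver RNA was measured on Affymetrix whole-transcript expression arrays, which carry biotin-labelled product made from total RNA and report the brightness of many short probes per transcript. The study holds 2 arrays, 1 from wild-type (WT) mice and 1 from mice lacking Iah1 in the whole body (KO). Per the labels' protocols, the animals were male, received the high-fat diet from 6 weeks of age for 12 weeks, and were without food for 4 hours before tissue collection, and 100 ng of RNA entered the labelling. Per the series' design text, RNA of 3 mice was combined for each array. The spread between mice is therefore averaged within each array and cannot be recovered, and no array was repeated.

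The deposited table gives 1 log2 value per probe set and array, and the submitters' processing notes name RMA and Affymetrix Expression Console 1.3.0. RMA subtracts background, makes the probe distributions of the arrays equal and summarises the probes of a probe set. It compresses differences of dim probe sets, so a fold change read from it can understate the change in RNA. A general shift of all transcripts between the genotypes would be removed by this step. The genome build behind the probe sets is not given in the sources used here, and no per-probe intensities or detection calls were used. Array precision is limited here by the number of arrays.

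The table held 41345 probe sets with values between 1.18 and 13.5. The platform annotation paired 23521 of them with 1 gene symbol and 1814 with several, and 16010 had no gene in it. Only probe sets with 1 symbol were named, which left 22180 genes, 1082 of them with more than 1 probe set. Gene identifiers matched the RefSeq table of assembly GRCm38.p6 for 21994 genes, and no symbol changed. Coordinates are not printed, since the build of the array annotation is not known, and that table served only for names and for the order of genes along a chromosome.

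Gene values were the mean of the log2 values of a gene's probe sets. Genes entered the comparison where the higher of the 2 arrays reached the median of all genes' higher values, 4.68 on the log2 scale, and 11090 genes did. The difference was KO minus WT on the log2 scale. With 1 array per genotype there is no residual spread, so no test of the genotypes was made and no p-value is given. Genes were counted by size, at a difference of 1.5-fold (0.58 on the log2 scale) or more. The words higher and lower describe the 2 arrays. Where 1 array lay below the filter, genes were ranked and counted by the RMA values and the printed fold takes the filter in place of the lower value. The only error that 2 arrays hold is the disagreement between probe sets of 1 gene, whose standard deviation was 0.25 on the log2 scale for a single probe set's difference (604 genes). It covers measurement by different probes, not mice, labelling or hybridisation.

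40 gene lists were fixed before the data were examined, on lipid, sterol, bile acid and glucose metabolism, drug metabolism, sex-biased genes, clock, stress, inflammation, matrix, cell cycle, mitochondria, genes near Iah1, and markers of hepatocytes, their zones and other cell types that liver tissue can hold. Members passing the intensity filter were used. For each list with at least 4 such members, the median difference was placed among the medians of 10000 random lists of equal size, matched in 20 bins of mean signal. A list is said to stand apart at or below percentile 2.5 or at or above 97.5. The percentile describes these 2 arrays and is not a test of genotype, and genes of a pathway vary together, which makes extreme percentiles more frequent than for independent genes. 33 lists were ranked and 7 had too few members.

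The genes named were also set by a rule fixed before the data were examined. They are Iah1 and Nnt, the 12 genes with the largest difference each way after leaving out predicted gene models, receptor and immunoglobulin segment families and small RNAs, and from each list up to 4 members with the largest absolute difference. Alternatives were another fold threshold, no filter or a filter at the 75th percentile, a loess fit (span 0.4) of the difference on the mean signal, quantile normalization again, subtraction of the median difference, the brightest probe set of a gene, the list mean, and random lists matched in 5 bins.

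The counting and list steps were tested on simulated data for 11090 genes of which 200 were changed. At the 1.5-fold threshold, 95% of the 100 genes changed 2-fold and 49% of the 100 genes changed 1.5-fold were recovered, and 3.57% of the unchanged genes were counted. The 49% follows from a change set at the threshold itself. The simulated spread was drawn from the observed differences, so the 3.57% follows the observed share and is no independent error rate. Of 100 simulated lists of 15 unchanged genes, 6% stood apart, and 88% did after a shift of 0.2 on the log2 scale. Each was placed among 1000 random lists. The 6% need not hold for the real lists, whose genes vary together. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6.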

Results

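Gene expression was profiled in the liver of male mice with and without Iah1 after 12 weeks of high-fat feeding. Iah1 encodes a homologue of a yeast esterase that hydrolyses isoamyl acetate. Each genotype was represented by 1 array that carried the pooled RNA of 3 mice, so every value below is a single measurement of a pool with no replicate error. The 2 arrays had similar distributions, with a median of 4.08 in WT and 4.10 in KO over 41345 probe sets. Their values correlated with a Pearson's r of 0.983 across probe sets, which are not independent replicates. The median difference of the 11090 genes above the intensity filter was -0.02 on the log2 scale.

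The first question was whether the targeted transcript was lost. Iah1 was the gene with the largest difference among those above the filter, at 8.59 in WT and 3.90 in KO, a difference of -4.69 on the log2 scale or 25.8-fold between the RMA values. The KO value lay below the intensity filter of 4.68 and is not shown to be above background; against that filter Iah1 was at least 15-fold lower. For other genes with 1 array below the filter, a fold is given against the filter in the same way, while log2 differences are those of the RMA values. Such a fold is a lower bound for the RMA values only. The filter is no detection limit and the bound leaves out measurement error, so a bound close to 1 does not by itself show a difference. Genes that flank Iah1 on chromosome 12 in the RefSeq annotation of GRCm38.p6 did not share this difference. Cpsf3, the next protein-coding gene on one side, differed by -0.05 and Adam17, the next on the other side, by -0.18. Of 14 measured genes in the list of Iah1 neighbours, 11 passed the filter and none of these reached a 1.5-fold difference, and the largest were -0.40 for Nol10 and -0.39 for Taf1b. Nnt, which is truncated in the C57BL/6J substrain, was at 8.96 in WT and 8.93 in KO.

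The second question was which other liver genes differed between the pools. At 1.5-fold, 163 genes were higher and 272 were lower in KO, which is 1.47% and 2.45% of the genes compared. With 1 array per genotype the counts do not separate change from measurement. At 2-fold the numbers were 15 and 34. After Iah1, the lower genes were led by Gadd45g, a stress-inducible growth-arrest gene, which was 3.89-fold lower. Mt2, a metallothionein that binds zinc and copper, was 2.99-fold lower (9.47 in WT and 7.89 in KO), and its neighbour Mt1 was 2.18-fold lower. The acute phase gene Orm3 was 2.84-fold lower and the serpin pseudogene Serpina4-ps1 2.92-fold lower. The other 7 of the 12 genes were below the filter in KO. They were the costimulatory receptor gene Cd86 (at least 2.08-fold lower), the interferon-inducible Ifi207 (at least 1.49-fold), the kinase gene Mapk13 (at least 1.39-fold), the macrophage elastase gene Mmp12 (at least 1.33-fold), Zfp932 (at least 1.28-fold), and Pomgnt2 and Cyp3a44 (both at least 1.04-fold).

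The genes with the largest increase were dimmer. Terc, the RNA component of telomerase, was 2.36-fold higher in KO (5.19 in WT and 6.43 in KO), and the ephrin gene Efnb3 was 2.04-fold higher. The other 10 of the 12 named genes had a WT value below the intensity filter. Against the filter they were higher by at least 1.97-fold for Map1b, 1.67-fold for the opsin gene Opn3, 1.54-fold for Vstm4, 1.34-fold for the kisspeptin receptor gene Kiss1r, 1.24-fold for the eotaxin gene Ccl11, 1.21-fold for the homeobox gene Hoxb6, 1.06-fold for Serp2 and 1.02-fold for the antisense transcript Kank4os and for Rbm12b1. The keratin gene Krt17 only just passed the filter in KO (4.68). The spread of differences fell with signal, from a standard deviation of 0.36 in the dimmest of 4 equal groups of genes to 0.16 in the brightest. In that brightest group 2 genes were higher and 18 lower at 1.5-fold.

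**Figure D1:**
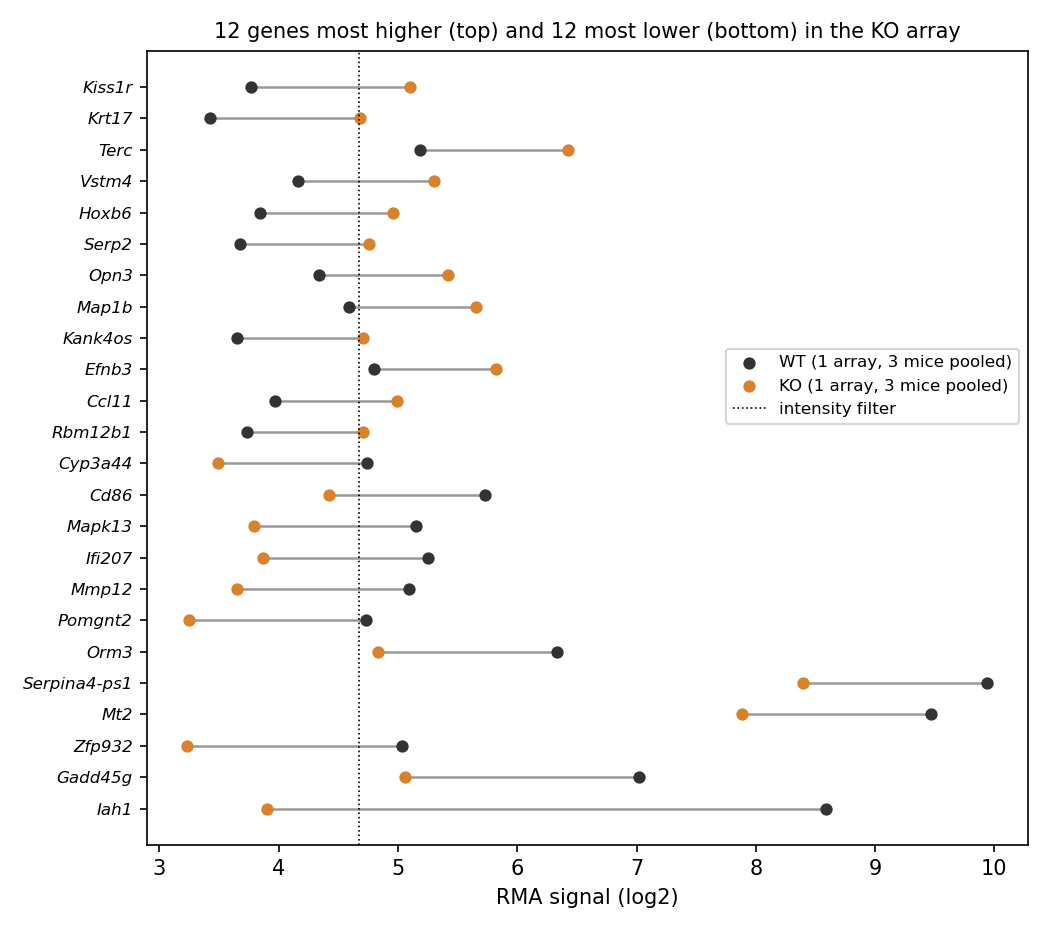
RMA signal on the log2 scale (horizontal axis) of the 12 genes with the largest positive and the 12 with the largest negative difference, with 1 point for the WT array and 1 for the KO array of each gene and a dotted line at the intensity filter of 4.68. Iah1 spans 8.59 to 3.90, and 10 of the 12 genes higher in KO start below the filter in WT.

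Genes of fatty acid synthesis were higher in the KO array, and their list was among the 14 of 33 that stood apart from random lists (1.65 would do so by chance if genes were independent). Of 14 members of the lipogenesis list that passed the filter, 12 lay above 0, and the median difference of 0.24 exceeded all 10000 matched random lists. Those below 0 were the transcription factor genes of this pathway, Srebf1 (-0.10) and Mlxipl (-0.08). Fasn, the fatty acid synthase gene, was the member past 1.5-fold, at 9.60 in WT and 10.2 in KO (1.52-fold). Acly, which supplies cytosolic acetyl-CoA, was 1.35-fold higher, Acacb, an acetyl-CoA carboxylase, 1.33-fold, and Me1, the malic enzyme that supplies NADPH, 1.33-fold. Genes of triglyceride synthesis had a median of 0.14 (percentile 99.8, 10 of 12 above 0), with the monoacylglycerol acyltransferases Mogat2 at least 1.64-fold and Mogat1 1.44-fold higher, and Gpam, which starts glycerolipid synthesis, 1.16-fold. Mogat2 was below the filter in WT. The triglyceride list did not stand apart with the stricter intensity filter (percentile 96.8) or with the brightest probe set of each gene (percentile 93.8).

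Cholesterol synthesis genes were higher by a small amount, with a median of 0.10 (percentile 99.9) and 15 of 20 members above 0, none past 1.5-fold. Srebf2, the transcription factor of this pathway, was 1.35-fold higher, Insig1 1.29-fold, and the mevalonate pathway genes Pmvk and Fdps both 1.24-fold. The PPAR-alpha and peroxisomal list had a median of 0.08 (percentile 99.0, 11 of 17 above 0). In it the hormone gene Fgf21 was 1.57-fold higher (4.70 in WT and 5.35 in KO), the acyl-CoA thioesterase genes Acot4 and Acot3 were 1.44-fold and 1.27-fold higher, and Pex11a 1.21-fold. The 2 probe sets of Acot4 disagreed, at 0.15 and 0.89, and the list did not stand apart with the stricter intensity filter (percentile 80.6). Apolipoprotein and lipoprotein assembly genes had a median of 0.07 (percentile 99.1, 12 of 15 above 0), with Apoa4 1.37-fold higher and Tm6sf2 1.29-fold higher, against Apoc3 at 1.32-fold and Pltp at 1.28-fold lower. By their mean of 0.05 they did not stand apart (percentile 95.4).

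Other lipid lists did not stand apart from random lists. The lipid droplet and lipolysis list had a median of 0.02 (percentile 84.0), with Cidea at 0.38, G0s2 at 0.24, Plin4 at -0.28 and Plin5 at -0.23. The 2 probe sets of G0s2 disagreed, at -0.03 and 0.51. Fatty acid uptake and activation had a median of -0.07 (percentile 11.5), with the lipoprotein receptor gene Vldlr at -0.57, the lipoprotein lipase gene Lpl at -0.44, Acsl4 at -0.32 and Fabp4 at -0.25. Lpl was below the filter in KO, and its 2 probe sets disagreed, at -0.82 and -0.06. The list of PPAR-gamma targets linked to fatty liver shares 8 of its 10 members with other lists, among them Vldlr and Lpl. It had a median of -0.12 (percentile 8.92) and a mean of -0.04, with 5 of 10 above 0, Mogat1 at 0.52 and Aqp7 at 0.42. Mitochondrial fatty acid oxidation had a median of 0.03 (percentile 92.8), and its members stayed between -0.11 for Etfdh and 0.14 for Cpt1a, the carnitine palmitoyltransferase that admits fatty acids to the mitochondrion, with Cpt2 and Hadh both at 0.12.

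Bile acid and glucose lists did not stand apart as a whole but held single genes past 1.5-fold. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 1.90-fold lower in KO (9.01 in WT and 8.08 in KO), while the sterol transporter gene Abcg5 was 1.33-fold lower and the nuclear receptor gene Nr0b2, a repressor of Cyp7a1, and the transporter gene Slco1a4 were both 1.27-fold higher. This list had a median of 0.01 (percentile 77.3) and a mean of -0.04. In the gluconeogenesis, glycogen and insulin list, Igfbp1, which insulin represses, was 1.75-fold lower, the glycogen-targeting subunit genes Ppp1r3g and Ppp1r3c were at least 1.15-fold (below the filter in KO) and 1.31-fold lower, and Irs2 was 1.24-fold lower, with a list median of 0.01 (percentile 72.3) and a mean of -0.08.

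The esterase list was included because Iah1 belongs to this class of enzyme. By RMA values 3 of 22 members were lower and none was higher at 1.5-fold. Ces3b was 1.56-fold lower, Ces2b and Ces4a were below the filter in KO (at least 1.08-fold and 1.01-fold lower), and Ces1d was 1.24-fold higher. Most members, 13 of 22, lay above 0, the list median was 0.04 (percentile 92.9) and its mean -0.05, and with the stricter intensity filter the list stood apart as higher (median 0.06, percentile 98.9). Cytochromes P450 of drug metabolism had a median of 0.00 (-0.0035, percentile 51.9), with Cyp3a44 and Cyp2c40 below the filter in KO (at least 1.04-fold and 1.31-fold lower), Cyp2c54 1.39-fold lower and Cyp3a59 1.40-fold higher. Conjugation enzymes had a median of 0.06 (percentile 99.2, 17 of 27 above 0), with Ugt2b37 at least 1.25-fold (below the filter in WT) and Gstm3 1.49-fold higher and Sult1b1 1.43-fold and Gstm4 1.29-fold lower. Members of these families are close copies of each other, so probe sets can share signal and single members are uncertain.

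Genes with higher expression in male than in female liver were lower in the KO array. The median of 17 members was -0.25, below all 10000 random lists, and 13 lay below 0. Hsd3b5, a male-specific steroid dehydrogenase, was 1.57-fold lower, the complement gene C6 1.43-fold, the fatty acid hydroxylase gene Cyp4a12a 1.38-fold and Susd4 1.38-fold. The female-biased list did not stand apart (median 0.02, mean -0.07, percentile 72.5), except as higher without an intensity filter (percentile 98.4). Its members went both ways. Cyp3a44 and Cyp2c40 were lower, both below the filter in KO, while Cyp17a1 was 1.55-fold and Acot3 1.27-fold higher.

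Markers of 2 non-parenchymal cell types were lower in KO. All 13 markers of liver sinusoidal endothelium lay below 0, with a median of -0.45, and 5 were past 1.5-fold. The hyaluronan receptor gene Lyve1 was 1.77-fold lower (7.80 in WT and 6.97 in KO), the angiopoietin receptor gene Tek 1.58-fold, Oit3 1.54-fold and the cadherin gene Cdh5 1.53-fold. Macrophage and Kupffer cell markers had a median of -0.47, with 14 of 16 below 0 and 3 past 1.5-fold. The complement gene C1qb was 1.75-fold lower (8.90 in WT and 8.10 in KO), Vsig4 1.64-fold, Adgre1, which encodes F4/80, 1.59-fold, and the endotoxin co-receptor gene Cd14 at least 1.23-fold (below the filter in KO). Both medians lay below all 10000 random lists. Hepatic stellate cell markers had a median of -0.17 (percentile 3.20), with the retinol acyltransferase gene Lrat at -0.52, Ngfr at -0.39, Pdgfrb at -0.29 and Des at 0.93, the last below the filter in WT. That list stood apart as lower after the loess fit (percentile 2.12) and with the brightest probe set of each gene (percentile 2.0). Hepatocyte markers had a median of -0.05 (percentile 12.0), with Serpina1e at -0.49 and Serpina1b at -0.17, while the abundant Ahsg and the transcription factor gene Hnf4a both differed by -0.07.

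The interferon and cytokine lists were lower by their medians in the same array as the macrophage and endothelial markers. Interferon response genes had a median of -0.17 (percentile 0.12, 19 of 24 below 0), with Ifit3 1.93-fold, Xaf1 1.46-fold, Oasl2 1.36-fold and Zbp1 1.35-fold lower. Of 20 measured genes in the cytokine and chemokine list, 13 passed the filter. Their median was -0.28 (percentile 0.11), with 9 below 0 and 4 above, up to Ccl5 at 0.38. The adhesion molecule genes Icam1 and Vcam1 were 1.67-fold and 1.31-fold lower, the chemokine gene Cxcl16 1.67-fold and Tgfb1 1.35-fold lower. This list did not stand apart with the stricter intensity filter (percentile 7.97). The acute phase list had a median of -0.05 (percentile 8.94) and a mean of -0.21. It stood apart as lower by that mean (percentile 0) and under quantile normalization again (median -0.07, percentile 1.38). Its 4 members lower by 1.5-fold or more were Mt2, Orm3, Mt1 and the serum amyloid gene Saa2 (1.78-fold lower), while Saa3 was the 1 member higher, at 0.59. Matrix and fibrosis genes had a median of -0.00 (-0.0017, percentile 63.8), with Mmp12 as above, the metalloproteinase inhibitor gene Timp2 at 1.82-fold lower, Loxl1 at least 1.11-fold lower (below the filter in KO) and Col6a1 at 1.24-fold higher.

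**Figure D2:**
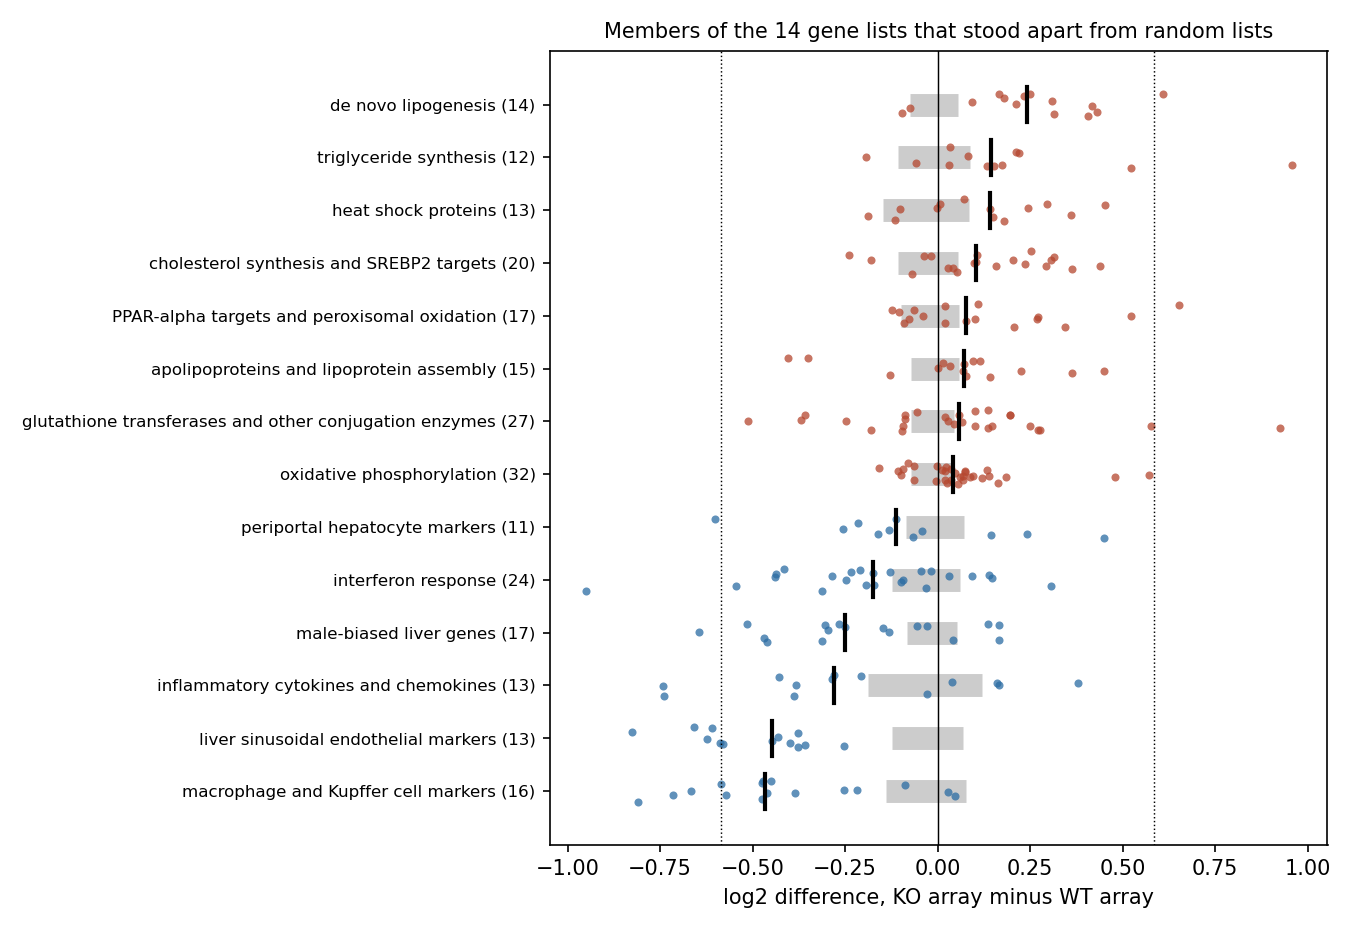
Log2 difference, KO minus WT (horizontal axis), of each member that passed the intensity filter (points) of the 14 lists that stood apart, with the list median (black bar), the central 95% of medians of 10000 matched random lists (grey) and 1.5-fold either way (dotted lines). The number of members is in brackets; the macrophage median lies at -0.47 and the lipogenesis median at 0.24, outside the grey ranges.

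Of the remaining lists, heat shock genes (median 0.14, percentile 99.7, 9 of 13 above 0) and oxidative phosphorylation genes (median 0.04, percentile 98.6, 23 of 32 above 0) were higher by small amounts, none past 1.5-fold. Hspa1a was at least 1.14-fold (below the filter in WT), Hspa8 1.28-fold, Hsph1 1.23-fold and Hspa1b 1.18-fold higher, and Hspa1a and Hspa1b are near-identical copies. Atp5o was 1.49-fold, Ndufb3 1.39-fold, Atp5c1 1.14-fold and Cyc1 1.12-fold higher. Periportal hepatocyte genes had a median of -0.11 (percentile 0.40, 8 of 11 below 0), with the urea cycle gene Ass1 1.52-fold and Ctsc 1.19-fold lower and Apoa4 and Cyp2f2 1.37-fold and 1.18-fold higher, and did not stand apart by their mean of -0.07 (percentile 10.1). Pericentral genes had a median of 0.03 (percentile 87.5), with Cyp7a1 as above, Axin2 at 0.48, Cyp2a5 at 0.47 and the glutamine synthetase gene Glul at 0.40. The 2 probe sets of Glul disagreed, at 0.00 (0.0029) and 0.80.

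The endoplasmic reticulum and integrated stress list had a median of 0.06 (percentile 97.2), with Fgf21 as above, Asns at 0.50, Ppp1r15a at -0.52 and Chac1 at -0.44. It stood apart as higher under 4 of 8 alternatives. Asns was below the filter in WT. Immediate early genes had a median of -0.08 (percentile 28.1), with Ier3 at -0.55, Myc at -0.45 and Dusp1 and Jun both at -0.37, with Ier3 below the filter in KO. Clock genes had a median of 0.02 (percentile 80.4), and the largest difference was 0.38 for Cry1, followed by Tef and Nfil3, both at 0.20, and Cry2 at 0.18. Cell cycle genes had a median of -0.02 and a mean of 0.03 (percentile 50.5), with Ccnb2 at 0.49, Cdc20 at -0.43, Mcm3 at 0.34 and Mcm4 at 0.31, where Ccnb2 was below the filter in WT and Cdc20 in KO. The Iah1 neighbour list as a whole had a median of -0.05 (percentile 34.8), with Odc1 at 0.26.

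Markers of other cells were mostly below the filter. None of 13 measured T and NK cell markers, 8 B and plasma cell markers or 11 neutrophil markers passed it in either array. Among cholangiocyte markers 2 passed, Sox9 and Krt23, both at -0.17. The erythroid marker Slc4a1 was at -0.44 and below the filter in KO, and the globin genes were not analysed here because their probe sets name several genes or none. Pancreatic acinar markers passing the filter were Ctrb1 at 0.70, Try4 at 0.28 and Cela1 at -0.17, and adipocyte markers passing it were Fabp4 at -0.25, Car3 at 0.18 and Lipe at 0.07.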

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

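Probe sets without a gene in the platform annotation, which no comparison above used, also differed between the arrays. Of 16010 such probe sets, 5098 passed the intensity filter. Of these, 556 were at least 1.5-fold higher in KO (10.9%) and 597 were at least 1.5-fold lower (11.7%), against 1.47% and 2.45% of the named genes. These shares set single probe sets against gene values and were not matched on signal. Among named genes, 273 of 2773 in the dimmest group were past 1.5-fold, against 20 of 2773 in the brightest. The shares therefore do not show that unnamed transcripts differed more. The extremes were 5.13 and -4.60 on the log2 scale. Outlying samples and differences between contrasts were not examined, since each genotype has 1 array and there is 1 contrast.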

How the results depend on the processing

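No paired analysis was possible because each genotype has 1 array, and for the same reason no array could be left out. Counts of genes followed the threshold and the filter. With 2-fold, 15 genes were higher and 34 lower, with 1.3-fold 538 and 851, without an intensity filter 572 and 576, and with the filter at the 75th percentile 18 and 61. Loess, quantile normalization again, median centring and the brightest probe set gave 158 to 187 higher and 239 to 273 lower genes, against 163 and 272. These scalings moved the median of all genes by 0.025 or less on the log2 scale. The difference of Iah1 stayed between -4.69 and -4.66. Of the 14 lists that stood apart, 9 did so under all 8 alternatives, and no list turned its direction while standing apart. The other 5 fell inside the random range under some: triglyceride synthesis with the stricter filter (median 0.083) and with the brightest probe set (0.060), PPAR-alpha targets (0.020) and inflammatory cytokines and chemokines (-0.21) with the stricter filter, and apolipoproteins (0.051) and periportal markers (-0.068) by the list mean. The cause was not tested. Not all of the 8 alternatives could change a list much. Median centring shifts list members and random lists alike, so it cannot change a percentile beyond the random draw. Loess and quantile normalization again changed values little, and the 5 bins only redrew the random lists. Among the 19 lists that did not stand apart, 5 did under at least 1 alternative, in 10 cases in all. The acute phase list was lower by its mean (-0.21) and under quantile normalization again (-0.07), and stellate markers were lower after loess (-0.16) and with the brightest probe set (-0.18). The endoplasmic reticulum stress list was higher with no filter, the stricter filter, loess and 5 bins (0.06 to 0.07), esterases with the stricter filter (0.06) and female-biased genes without a filter (0.12). Of 604 values of the 151 other named genes under 4 alternatives, 4 moved by more than the probe set disagreement, all where probe sets of a gene disagree (G0s2 0.51, Lpl -0.82, Acot4 0.15 and Glul 0.0029 by the brightest probe set), and no gene past 1.5-fold changed sign. Loess (fit at most 0.035) and median centring (0.025) could not move a gene that far. Quantile normalization again repeats a step of RMA. The brightest probe set can change only genes with more than 1 probe set. The share of 604 is therefore no measure of stability. Ass1 fell under 1.5-fold after loess, quantile normalization again and median centring. Of the 435 genes past 1.5-fold, 273 lie in the dimmest of 4 equal groups.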

Other observations

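The second lists and the growth hormone and glucocorticoid lists were added after the first results were seen, and the trend, clock, fed-state, female-pattern and pooling tests and the bright genes were chosen after the values they use were seen. Among the 5545 genes of highest signal (the stricter intensity filter), the transcriptional repressor gene Bcl6 was 1.83-fold higher in KO (7.18 in WT and 8.06 in KO), the bile acid transporter gene Slc10a2 1.77-fold higher, the mitochondrial ribosomal gene Mrps16 1.70-fold and the ephrin gene Efna1 1.64-fold. In the same set the calcium-binding S100a11 was 2.30-fold lower, Adam23 2.25-fold lower, the hepatocyte transcription factor gene Onecut1 2.23-fold lower (8.33 in WT and 7.17 in KO) and the macrophage scavenger receptor gene Msr1 2.21-fold lower. They are the 4 largest each way beyond genes already named, under the same exclusions. Glucocorticoid-induced genes had a median of -0.12 (percentile 5.98, 7 of 10 below 0), with Sgk1 at -0.42, Klf9 at -0.37 and Cdkn1a at 0.29.

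Endothelial and macrophage markers were both lower. Little intensity-dependent difference was left by the normalization. The loess fit of the difference on signal reached 0.035 at most, against medians of -0.45 and -0.47. RMA equalises the probe distributions, which keeps such a fit small in advance, so it checks the normalization and does not test the cause. A change only in the few genes chosen is argued against, since second lists sharing no gene with the first both lay at percentile 0. For endothelium the second median was -0.34 (15 of 21 below 0, from Ehd3 at -0.99 to Egfl7 at 0.16). For macrophages it was -0.35 (18 of 19 below 0, from Fcgr1 at -0.73 to Lgals3 at 0.42). A lower share of all non-parenchymal cells alike may underlie the pattern, and stays open: the second stellate and mesenchymal list had a median of -0.12 (percentile 8.76), its members went both ways, and the first stellate list lay at percentile 3.20 and stood apart under 2 alternatives. A chance difference between the mice pooled cannot be told apart from genotype with 1 array each, and the genotype itself stays untested.

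Lipogenic genes were higher. The loess fit reached 0.035 at most, against a median of 0.24. As above, RMA keeps this fit small in advance, so it checks the normalization and does not test the cause. A clock phase shift that moves clock genes as much as lipogenic ones is argued against as the whole cause: 14 of 15 clock genes differed by less than the lipogenic median (median absolute difference 0.052, upper quartile 0.16), with Cry1 at 0.38 the exception. A KO pool closer to the fed state could raise these genes, and the values pull both ways. Of genes that insulin represses, Igfbp1 was at -0.81, Irs2 at -0.31, G6pc at -0.18 and Pck1 at -0.07 (median -0.25). The list of 19 genes that holds them had a median of 0.01. PPAR-alpha targets, which fasting induces, lay at percentile 99.0 with 11 of 17 above 0, or at percentile 80.6 with the stricter intensity filter. Furthest above 0 were Fgf21 (0.65), Acot4 (0.52, probe sets disagreeing) and Acot3 (0.34). Other targets lay near 0, with Pdk4 at 0.08, Angptl4 at -0.06, Ehhadh at -0.09 and Cyp4a14 at -0.10. The list did not rise as a whole, so its percentile cannot decide. Genotype and chance between mice stay open.

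Male-biased genes were lower. The loess fit reached 0.035 at most, against a median of -0.25, and again checks the normalization without testing the cause. Weaker growth hormone and STAT5 signalling is a candidate explanation that stays open. A list of genes induced by or part of this signalling had a median of -0.10 at percentile 11.8, with 8 of 9 below 0. Socs2 was at -0.88 and Igf1 at -0.30, but the list did not stand apart. It also holds Ghr (-0.003), Stat5a (-0.10) and Stat5b (-0.27), which are parts of the pathway and not its targets, so its percentile cannot decide. A shift towards a female pattern was not decided either, with female-biased genes at percentile 72.5 and members going both ways (6 of 12 above 0). The 2 largest decreases, Cyp3a44 and Cyp2c40, were below the filter in KO. Cyp17a1 (0.63) and Acot3 (0.34) were higher, and the brighter Cyp2b9 (0.09), Cyp2a4 (0.07) and Cyp2b13 (-0.07) lay near 0. Genotype and chance between mice stay open here as well.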
